A study of Danio rerio with 2 samples.

How the data were processed

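Whole zebrafish embryos of the AB strain at 3 days post fertilization were homogenized, passed through a cell strainer and profiled by droplet-based 3' single-cell RNA sequencing. Both genotypes carried a GFP reporter driven by a globin control region, which labels red blood cells. Each genotype, wild type and mfrn1 mutant, was represented by 1 library made from 10 embryos. The deposited values were raw UMI counts per gene and barcode, with no normalization. Per the file headers they were made with Cell Ranger 7.0.1, and per the submitters' processing notes the genome build was GRCz11. An EGFP sequence was among the 27598 features. The lowest total of any deposited barcode was 500 UMIs in both libraries, so the barcodes had been restricted to cells before deposit. The mutant allele, the sequencing batch and the embryo of origin of each cell were not given in the sources used here.

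The wild-type library held 17939 barcodes and 93989402 UMIs, with a median of 3165 UMIs and 1207 genes per barcode. The mutant library held 16347 barcodes and 78887145 UMIs, with a median of 2829 UMIs and 1295 genes. Features that shared a symbol were summed (549 symbols on 1257 features), which left 26890 symbols. Gene symbols are those of the deposited feature table. Synonyms were looked up in a reference gene table of another assembly, GRCz12tu, from which no coordinates were taken.

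Cells with at least 200 detected genes and at most 20% mitochondrial UMIs were kept, which removed more of the mutant library (15149 of 16347 barcodes passed both limits) than of the wild type library (17759 of 17939). Doublets were called with Scrublet, as run in scanpy 1.11.5, in each library with its automatic threshold. The threshold was 0.158 in the wild-type library and removed 24.6% of barcodes. It was 0.358 in the mutant library and removed 2.61%, against expected rates of 14.35% and 13.1%. After both steps 13417 wild-type and 14736 mutant cells remained, with medians of 2966 and 3119 UMIs.

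The libraries were clustered together without batch integration. Counts were scaled to 10000 non-globin UMIs per cell and log-transformed. From these, 2000 variable genes, 30 principal components and 15 nearest neighbours were used for Leiden clustering (leidenalg 0.10.2, igraph 0.11.9) at resolution 1. Globin, mitochondrial and ribosomal protein genes and the S phase and G2/M lists were left out of the variable genes. A cluster was named for the best-scoring of 40 marker sets when at least 3 of its markers were among its top 50 genes by fold; erythroid-like clusters needed 3 markers other than globins. A cluster that met this stayed unnamed if its top 10 genes held more markers of another type than of its own (clusters 32 and 37). A cluster of low depth with none of its own markers among its top 10 genes also stayed unnamed (cluster 29). Of 51 clusters, 25 received a name and 26 stayed unnamed. A rule added after the data were seen left a cluster unnamed when 3 markers of another type were among its top 10 genes. It applied to cluster 38, with leading genes of melanophores and retinal pigment epithelium, which held 94 wild-type cells (0.701%) and 38 mutant cells (0.258%). Unnamed clusters were compared by number. Genes and lists were compared in the 22 other classes and clusters with at least 100 cells per library.

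For each class or cluster, UMIs were summed per library and expressed as CPM, UMIs scaled to a common total of non-globin UMIs; globins were expressed over all UMIs. Values are given as log2 of mutant over wild type. With 1 library per genotype there was no replicate check, so no test between genotypes was made and no p-value was computed. Shares of cells carry exact Clopper-Pearson intervals, and folds carry exact conditional binomial intervals, all at 95%. They cover counting error only, with every UMI of a class taken as independent, not the variation between cells, embryos or preparations. For a gene with 0 counts in a library, the fold was computed against a floor of 3 counts over the class. Such folds are given as at least that size, on this floor, and the end of the 95% interval is a somewhat smaller fold. Intervals of list medians came from Poisson redraws of the counts.

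The cell classes, the 23 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The lists were embryonic globins, adult globins, heme synthesis, heme breakdown and export, iron uptake and storage, iron-sulfur cluster assembly, nuclear respiratory chain, mitochondrial genome, S phase, G2/M, G1 and cell cycle exit regulators, and erythroid regulators and membrane. The others were integrated stress response, mitochondrial chaperones and proteases, p53 targets and apoptosis, antioxidant response, hypoxia targets, glycolysis, mitophagy and autophagy, dissociation stress, interferon and inflammation, eye crystallins, and pancreatic proteases. The last 2 lists and the dissociation list served as controls for RNA of other cells and for handling. For each list the median log2 fold of members with at least 20 UMIs over both libraries was computed, with its percentile among 10000 random lists of the same size matched on mean expression. The percentile describes these libraries and is not a test. A member was counted as higher or lower at a fold of at least 1.25. Neuron markers, 1 of the cell type marker sets, were summarised the same way in erythroid-like cells after the data were seen.

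Named genes were chosen by rule. All measured members of the heme synthesis list and slc25a37 could be named, and for other lists the members with the most UMIs or the largest fold bound. In erythroid-like cells the 12 genes higher and the 12 lower in the mutant library with the largest fold bound were named. They needed at least 100 UMIs in the higher library, a fold of at least 1.5 and, in the higher library, a level at least 0.5 times that in all other cells. Library-wide genes were the 5 each way with the largest median fold among genes shifted at least 1.5-fold the same way in every class with 50 UMIs or more, over at least 5 classes. Class-specific genes were the 5 class and gene pairs each way with the largest fold bound whose median fold over the other classes was under 1.25.

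The share of cells with cell cycle transcripts was computed after thinning every cell to 300 non-globin UMIs, as the share with at least 2 UMIs of a list. The exact hypergeometric expectation was used in place of a random draw, so the counts of positive cells are expected numbers rounded to whole cells. This replaced a single draw after the result of that draw had been seen to depend on the seed.

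Alternatives covered the gene and mitochondrial limits, doublet removal, clustering resolution and features, the scaling total, subtraction of ambient RNA, equal weight per cell, the UMI minimum of list members and the thinning depth. Chosen after seeing the data were cells with at least 10% globin UMIs, doublets removed at the expected rate in both libraries, all deposited barcodes with at least 10% globin UMIs without clustering, both libraries limited to globin at 10 to 50% of UMIs, cells with fewer than 10 neuron marker UMIs, and shares of the other classes under the other filter, doublet and clustering settings. Taking all UMIs as the total added 1.24 to every log2 fold in erythroid-like cells, because globins took a larger share of the wild-type UMIs, and median-of-ratios scaling added -0.49. The median log2 fold of measured genes in these cells was 0.27 with the scaling used.

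The fold computation was tested on simulated Poisson counts with known folds, drawn from the class sums and so without variation between cells. Of 3062 genes simulated for erythroid-like cells, intervals held the true value for 94.4% of genes at 4-fold, 100% at 2-fold, 96.2% at 0.5-fold, 98.1% at 0.25-fold and 95.95% of unchanged genes, and 94 of 100 lists of unchanged genes lay in the central 95% of random lists. For all other cells, with 18096 genes, the interval held the true value for 90.7% of genes at 4-fold, 95% at 2-fold, 94.3% at 0.5-fold, 96.2% at 0.25-fold and 95.4% of unchanged genes, and 90 of 100 lists of unchanged genes lay in the central 95%. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and anndata 0.12.19, and figures matplotlib 3.10.9.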

Results

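Single-cell transcriptomes were obtained from 3-day-old zebrafish embryos, either wild type or mutant for mfrn1 (slc25a37), which encodes mitoferrin 1, the carrier that brings iron into the mitochondria of red blood cell precursors. Each genotype gave 1 library from 10 pooled embryos, with 93989402 UMIs over 17939 barcodes in the wild type and 78887145 UMIs over 16347 barcodes in the mutant. After filtering, 13417 wild-type and 14736 mutant cells were compared. The series asks which lineages, erythroid and other, differ in the mutant, which genes are expressed differently, and whether erythroid cells progress through the cell cycle. No difference below has a replicate check, and each compares these 2 libraries.

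The targeted gene was lower in the erythroid-like cells of the mutant library. There, slc25a37 had 660 UMIs (254 CPM) in the wild type and 88 UMIs (106 CPM) in the mutant, a log2 fold of -1.27 (-1.61 to -0.95). In cells of the class with at least 10% globin UMIs the log2 fold was -1.14, from 659 and 67 UMIs. In all other cells its level was low, at 160 UMIs (3.12 CPM) and 280 UMIs (3.84 CPM), and neural progenitor-like cells held 64 and 40 of these UMIs. Its paralog slc25a28 (mitoferrin 2), which supplies mitochondria of other tissues, was higher in the mutant erythroid-like cells, with 32 against 42 UMIs (log2 2.03, 1.33 to 2.74). The lesion is not given in the sources used here, so the change it would bring to the 3' count of slc25a37 is not known. The lower level therefore does not by itself check the label. With all UMIs as the total the log2 fold of slc25a37 was -0.03.

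Red blood cells were far scarcer in the mutant library. Erythroid-like cells made up 8.45% of wild-type cells (1134 cells, 95% interval 7.99 to 8.94%) and 0.489% of mutant cells (72 cells, 0.383 to 0.615%), a share 17.3-fold lower in the mutant (13.6 to 22.3). The class was held by different clusters in the libraries. Cluster 15 had 594 wild-type and 24 mutant cells, cluster 17 had 539 and 1, and cluster 44 had 1 and 47, so cluster 44 was nearly all from the mutant library and may be that library rather than a cell type. Of the erythroid-like cells, 1129 wild-type and 56 mutant cells had at least 10% globin UMIs, while 5 and 16 had less; 2 cells of each library lay between 5 and 20%. Among all deposited barcodes, without clustering or doublet removal, 1315 of the wild type (7.33%) and 57 of the mutant (0.349%) had at least 10% globin UMIs.

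**Figure D1:**
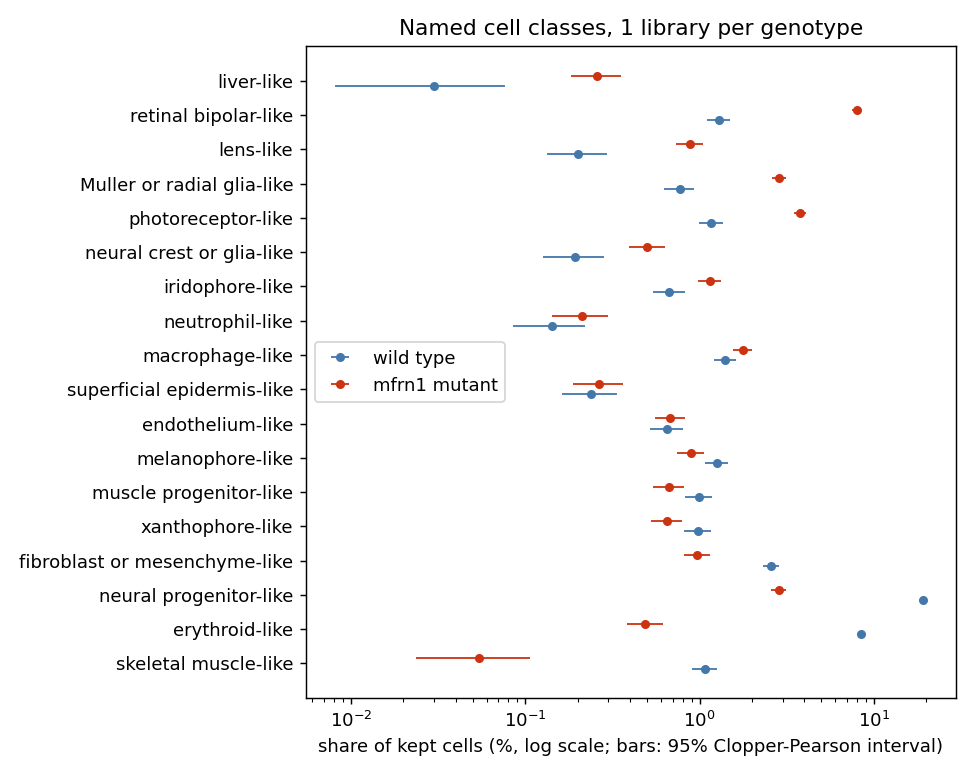
Share of kept cells in each named class (horizontal axis, percent, log scale) in the wild-type library (blue) and the mutant library (red), with 95% Clopper-Pearson intervals. Erythroid-like cells were at 8.45% and 0.489%, skeletal muscle-like cells at 1.07% and 0.0543%, and retinal bipolar-like cells at 1.29% and 7.97%; the fibroblast-like and macrophage-like differences each reversed in 2 alternatives.

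Globins took a smaller share of the UMIs of mutant erythroid-like cells, and these cells held more non-globin UMIs. The median of non-globin UMIs per cell was 1780 in the wild type and 9573 in the mutant, while the mean of globin UMIs per cell was 5112 and 4306 over the class and 5135 and 5458 in cells with at least 10% globin. Levels of other genes are relative to the non-globin UMIs, so a lower level is a smaller share and need not mean fewer UMIs per cell. Globins took 69.1% of all UMIs of the class in the wild type and 27.099% in the mutant, and the median per cell was 72.3% and 31.8%. In cells with at least 10% globin the pooled shares were 69.2% and 34.6%. All 9 measured embryonic globins had lower shares of UMIs in the mutant, from hbae5 (log2 -3.08, -3.29 to -2.88) to hbbe1.1 (log2 -0.65, -0.66 to -0.64). The most abundant, hbae3, an embryonic alpha globin, made up 21.3% and 9.02% of UMIs, and hbbe1.3, an embryonic beta globin, 18.2% and 4.89%. Within the globin UMIs alone, hbbe1.1 took a larger part in the mutant (15.6% and 25.4%) and hbbe1.3 a smaller part (26.4% and 18.1%). Both measured adult globins were lower too. hbaa1 had 112 UMIs and 1 UMI (log2 -3.93, -9.25 to -1.42), and hbba1 had 116 and 0 (at least 5.27-fold lower). The EGFP reporter had at least 1 UMI in 71.6% of wild-type (68.9 to 74.2%) and 73.6% of mutant erythroid-like cells (61.9 to 83.3%), so a difference was not detectable. In all other cells, which should lack it, 3.96% and 0.675% had an EGFP UMI, with 848 and 726 EGFP UMIs in all. Of all deposited barcodes, 414 of 17939 in the wild type and 45 of 16347 in the mutant had at least 10 EGFP UMIs. That share was 8.38-fold lower in the mutant (6.15 to 11.7), against 17.3-fold for erythroid-like cells. It also depends on depth. Median depth was 6976.5 UMIs per erythroid-like cell in the wild type and 14738.5 in the mutant, and 2774 and 3103 in all other cells.

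Heme synthesis genes were lower on balance in the mutant erythroid-like cells, led by alas2, the erythroid enzyme of the first step. Of 16 measured members 8 were lower, 3 higher and 5 between, with a median log2 fold of -0.36 (-0.53 to -0.21) at percentile 4.2 of matched random lists. alas2 had 13223 and 1421 UMIs (log2 -1.58). Enzymes of later steps were lower with this scaling and above 0 with all UMIs as the total: cpox (-1.17), hmbsa (-0.97), uros (-0.81), fech, which inserts iron into the porphyrin ring (-0.65), and urod (-0.53). The same held for the mitochondrial transporter abcb10 (-0.41). hmbsb (-0.30) and alad (-0.21) were too small in size to count as lower and also above 0 with all UMIs, and clpxa, a subunit of the protease complex that acts on ALAS, was at -0.63 (-1.36 to 0.04). The housekeeping form alas1 was at 0.92, frataxin (fxn) at 0.94 with 13 and 8 UMIs, clpxb at 0.61, ppox at 0.12, tmem14ca at 0.03 and the glycine carrier slc25a38b at -0.01. In cells with at least 10% globin the median was -0.17. It was 0.88 with all UMIs as the total, 0.19 among all barcodes with at least 10% globin and 0.05 in cells with globin at 10 to 50% of UMIs, so the direction of the list depended on these settings. alas2 stayed lower in all 15 alternatives (-2.07 to -0.23), each of which takes it relative to other UMIs. Its UMIs per cell were not compared, and mutant cells held more non-globin UMIs (medians of 1780 in the wild type and 9573 in the mutant).

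Ferritin-like genes were far higher in the mutant erythroid-like cells. The family fthl27 to fthl31, ferritin heavy chain-like genes for iron storage, summed to 3854 UMIs in the wild type and 31942 in the mutant, a 25.8-fold higher level. It was 36.3-fold higher in cells with at least 10% globin. In all other cells the family was 1.39-fold higher. The values of single members, such as fthl28 (log2 7.34) and fthl27 (3.24), are uncertain, because reads of related genes could have been split between them in the counting; their sequences were not compared here. The iron uptake and storage list as a whole had 9 members higher, 6 lower and 2 between, with a median of 0.64 (-0.05 to 1.26) at percentile 87.2. Ferritin heavy chain fth1a, its member with the most UMIs, was at -0.34, at 0.02 in cells with at least 10% globin and above 0 with all UMIs as the total. Of 2 members chosen after their values were seen, ncoa4, the receptor for ferritin turnover, was at -1.28, which all UMIs as the total brings to just below 0, and the transferrin receptor tfr1a was at -0.52, which turns to above 0 with all UMIs as the total. Heme breakdown and export genes had 3 of 5 members higher and none lower, with a median of 0.56 (percentile 65.7). In iron-sulfur cluster assembly, 15 of 23 members were higher, 2 lower and 6 between, with a median of 0.67 (0.35 to 0.83) at percentile 91.6. The chaperone hspa9 (3.13) and the desulfurase partner lyrm4 (2.17) were among the higher members; isca1 was at -0.55, above 0 with all UMIs as the total.

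**Figure D2:**
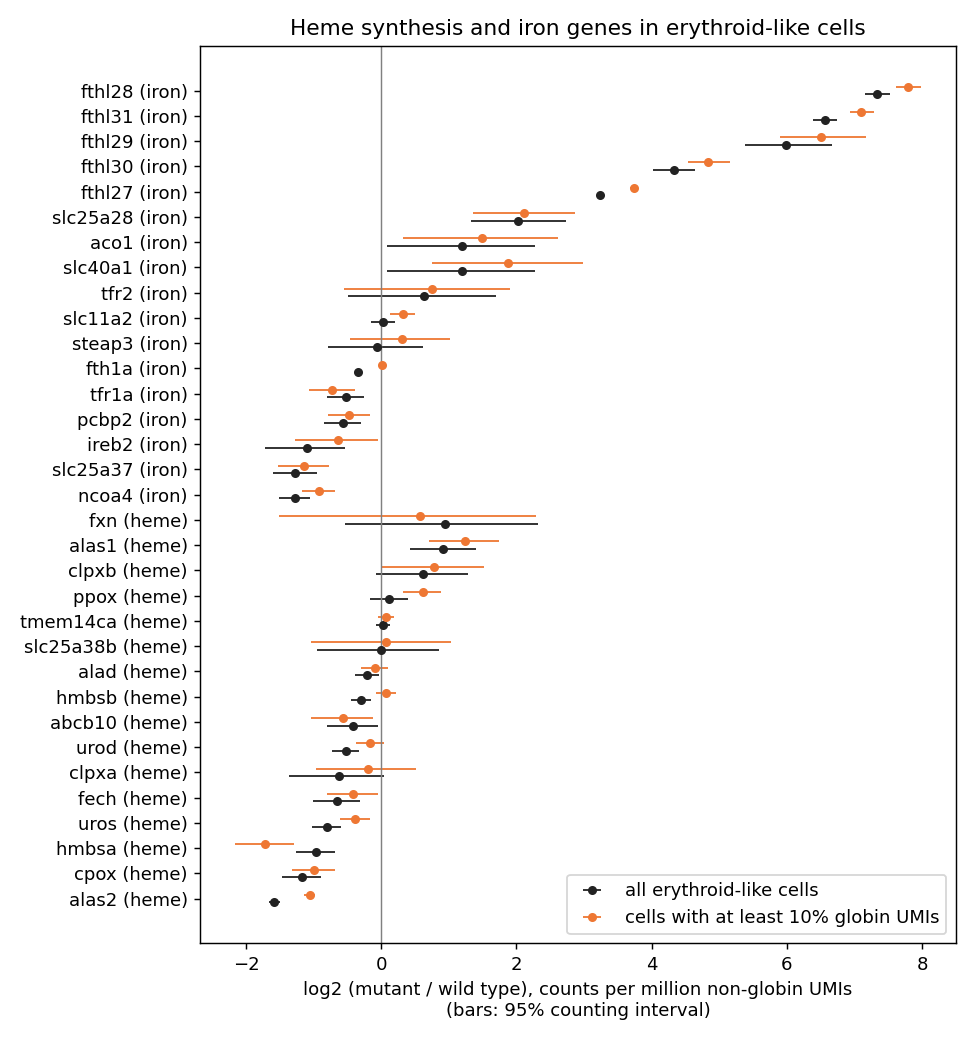
Log2 fold of mutant over wild type (horizontal axis) for measured heme synthesis and iron genes in all erythroid-like cells (black) and in those with at least 10% globin UMIs (orange), with 95% counting intervals. fthl28 lay at 7.34 and alas2 at -1.58; with all UMIs as the total every black point moves right by 1.24, which leaves only alas2, ncoa4 and slc25a37 below 0.

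Transcripts of the G2/M phase were lower in mutant erythroid-like cells, while those of S phase depended on which cells were included. For G2/M, 50 of 57 members were lower, 1 higher and 6 between, with a median log2 fold of -1.28 (-1.46 to -1.11), below all 10000 matched lists (percentile 0). Examples were ccnb3, a mitotic cyclin (-2.59), cenpe, a kinetochore motor (-2.32), lbr, a nuclear envelope receptor (-1.70), and cdk1, the mitotic kinase (-1.63). In cells with at least 10% globin the median was -1.61, and with all UMIs as the total it was -0.04. For S phase, 33 of 49 members were higher, 7 lower and 9 between, with a median of 0.70 (0.43 to 0.78) at percentile 95.2. Among them were the replication helicase gene mcm3 (1.86) and the sliding clamp pcna (0.80, and -1.90 in cells with at least 10% globin), while the ribonucleotide reductase subunit rrm2 was at -0.48 and above 0 with all UMIs as the total. Without the 5 wild-type and 16 mutant cells under 10% globin the S phase median was -1.03 (-1.28 to -0.72), with 4 members higher, 33 lower and 9 between. The S phase median was also below 0 with at least 100 genes (-1.04), at least 500 genes (-1.15) and at most 10% mitochondrial UMIs (-1.03). G1 and cell cycle exit regulators had a median of 0.16 (percentile 20.6), with 9 higher, 10 lower and 7 between, and of -0.49 in cells with at least 10% globin and -0.33 with median-of-ratios scaling. The median of the G1 and cell cycle exit regulators list in erythroid-like cells was -0.0728 without those holding at least 10 neuron marker UMIs. Within it the MYC-family gene mych (3.67) was higher, and mxi1, a MYC antagonist (-2.30), and the cyclin ccng2 (-2.81) were lower. mycb, also of the MYC family, was at 3.09 over all cells and -1.61 in those with at least 10% globin.

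The share of G2/M-positive cells was lower in the mutant at equal depth, within counting error. After thinning to 300 non-globin UMIs, an expected 251 of 1133 wild-type cells (22.2%, 19.8 to 24.7%) and 11 of 72 mutant cells (15.3%, 7.88 to 25.7%) had at least 2 G2/M UMIs, so a difference was not detectable at this depth. Unthinned shares went the other way, at 53.7% and 84.7%, with median non-globin depths of 1780 and 9573 UMIs; 1 wild-type cell was too shallow and left out. S phase UMIs were found in 83 of 1133 cells (7.33%) and 11 of 72 (15.3%) after thinning, against 39.0% and 75.0% before. In cells with at least 10% globin the thinned shares were 21.99% and 10.7% for G2/M and 7.18% and 3.57% for S phase, from 1128 and 56 cells, and the unthinned shares 53.6% and 82.1% for G2/M and 38.9% and 67.9% for S phase. The background in cluster 0, which stayed unnamed with neuron markers as its best match and had median depths of 3002 and 2948.5 UMIs, was 1.77% and 1.01% for G2/M and 0.826% and 1.26% for S phase after thinning, and 42.6% and 35.5% for G2/M and 33.8% and 35.4% for S phase before.

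Genes of the mature red cell were lower in the mutant, and genes of stress responses, mitochondrial protein folding and glycolysis were higher. Of 25 erythroid regulators and membrane genes 21 were lower and none higher, with a median log2 fold of -1.20 (-1.33 to -0.98) at percentile 0. They included the anion exchanger slc4a1a (-1.80), hemgn (-1.49), the erythropoietin receptor epor (-2.44) and the transcription factor klf17 (-4.20), whereas gata1a and lmo2, chosen after their values were seen, were both at 0.02. With all UMIs as the total the median of the erythroid list was 0.04. It was -0.76 in cells with at least 10% globin. In cells with globin at 10 to 50% of UMIs it was -0.48, with 13 members lower, 4 higher and 6 between. The integrated stress response had 18 of 27 members higher, 7 lower and 2 between (median 1.56, percentile 100), among them phgdh, of serine synthesis (4.16), ddit3 (CHOP, 3.87) and trib3 (2.85), with eif2ak1, the heme-regulated kinase, chosen after its value was seen, at -1.13 and above 0 with all UMIs as the total. Mitochondrial chaperones and proteases had 16 of 17 members higher and 1 lower (median 2.22, percentile 100), among them the chaperonin partner hspe1 (3.82) and the prohibitin phb2a (3.26). The antioxidant response had 16 of 21 higher, 2 lower and 3 between (median 1.92, percentile 100), with gclm, of glutathione synthesis (4.49), prdx1 (3.90) and txn (3.89). Its most abundant member, the red cell peroxiredoxin prdx2, was at -0.51 and above 0 with all UMIs as the total. Glycolysis had 15 of 18 higher, 2 lower and 1 between (median 2.35, percentile 100), with eno1a (4.03), gapdhs (3.35) and ldhba (2.88) among the higher. The size of the glycolysis median moved widely with the settings, from 0.75 to 3.59 over 17 alternatives. The medians in cells with at least 10% globin were 1.298, 1.69, 2.01 and 1.94 for the lists of stress response, chaperones, antioxidant response and glycolysis. In cells with globin at 10 to 50% of UMIs they were 2.33, 1.51, 2.03 and 1.68. Neuron markers were also higher in the mutant erythroid-like cells, with 11 of 16 measured markers higher, none lower and 5 between; their sum was 378 and 830 CPM (log2 1.13, 0.99 to 1.28), against 4466 and 7807 CPM in all other cells, and the marker with the most UMIs, elavl4, was at 2.26. Of the 692 neuron marker UMIs in the mutant class 558 lay in 10 cells. Without cells holding at least 10 such UMIs (11 wild-type and 10 mutant cells) the log2 fold of the sum was -0.65 (-0.92 to -0.38), or 0.58 with all UMIs as the total. These cells were left out by the same UMIs that were then summed, at an equal limit in both libraries. Mutant cells were deeper (medians of 9573 and 1780 non-globin UMIs in mutant and wild type), so the change of sign was partly built in. Without the same cells, the medians of the integrated stress response list in erythroid-like cells, the mitochondrial chaperones and proteases list in erythroid-like cells, the antioxidant response list in erythroid-like cells and the glycolysis list in erythroid-like cells were 1.57, 2.28, 1.95 and 2.496. Ribosomal protein genes took 39.3% and 31.6% of the non-globin UMIs of the class.

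Nuclear and mitochondrial genes of the respiratory chain went opposite ways. Of 44 nuclear-encoded members 42 were higher, 1 lower and 1 between, with a median of 1.06 (0.99 to 1.13) at percentile 99.99. Succinate dehydrogenase subunits sdha (2.72) and sdhb (2.46) and cyc1 (2.35) were among the highest. Of 13 genes of the mitochondrial genome 8 were lower, 2 higher and 3 between, with a median of -0.51 (-0.60 to -0.45); mt-co2 was at -1.26 and mt-cyb at -1.27, both just below 0 with all UMIs as the total. The mitochondrial median was 0.72 with all UMIs as the total. In all other cells it was 0.87, with all 13 members higher in the mutant library. The lists of respiratory chain, integrated stress response, chaperones, antioxidant response and glycolysis kept positive medians in all 17 alternatives.

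Other lists gave smaller or less certain differences. p53 targets and apoptosis had 9 higher, 9 lower and 4 between (median 0.02, percentile 23.5), with the ribosomal protein-like gene rps27l at 2.05. Hypoxia targets had a median of -0.17 (percentile 17.9), with 6 higher and 5 lower, and mitophagy and autophagy a median of -0.30 (percentile 3.17), with sqstm1 (2.78) higher and bnip3lb, a mitophagy receptor of maturing red cells, lower (-1.38). The hypoxia and mitophagy medians were 0.30 and 0.14 in cells with at least 10% globin and above 0 with all UMIs as the total, so neither direction held. Dissociation stress genes had a median of 0.69 (percentile 86.1), with 12 of 18 higher, among them the heat shock gene hsp90aa1.2 (2.57), and 4 lower. Interferon and inflammation had 5 measured members, 3 higher and 2 lower (median 0.85, percentile 88.0). The 2 lists that served as controls for RNA of other cells were lower in mutant erythroid-like cells, unlike the neuron markers, with eye crystallins at -1.73 (4 members) and pancreatic proteases at -2.20 (2 members), although in all other cells of the mutant library they were higher, at 4.099 and 2.76.

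**Figure D3:**
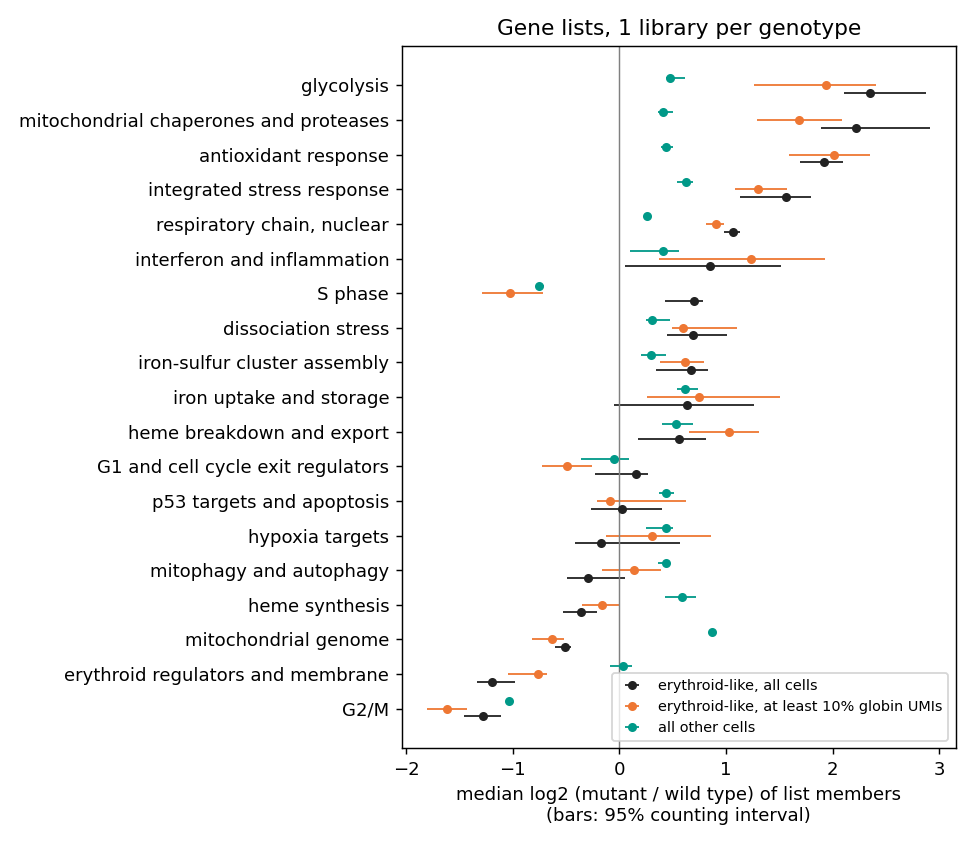
Median log2 fold of mutant over wild type (horizontal axis) of each gene list other than the globins with at least 5 measured members, in all erythroid-like cells (black), those with at least 10% globin UMIs (orange) and all other cells (green), with 95% counting intervals. Of these lists glycolysis (2.35) and mitochondrial chaperones (2.22) were highest and G2/M (-1.28) lowest in erythroid-like cells; S phase was 0.70 over all erythroid-like cells and -1.03 with at least 10% globin, and with all UMIs as the total every black point other than G2/M lies above 0.

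Among the single genes higher in mutant erythroid-like cells were genes of mitochondria, iron storage and stress. The 12 genes taken by the rule all had intervals above a log2 fold of 4.5. They were ociad2, a mitochondrial membrane protein (log2 9.65), fthl28 (7.34), fthl31 (6.57) and fthl29 (5.99) of the ferritin-like family, isg15, a ubiquitin-like interferon-response gene (7.20), atf5b, a transcription factor of the stress response (6.93), hbegfa, an EGF-family growth factor (6.89), pon1, a paraoxonase (6.70), and hspd1, the mitochondrial chaperonin HSP60 (5.22). The others were si:dkeyp-27c8.2, listed as mdp1 in the reference table (7.48), BX511021.1 (7.30) and si:dkey-44g23.5 (5.12). isg15 had 10 UMIs in 2 wild-type cells and 473 UMIs in 43 mutant cells. BX511021.1 was also higher in all other cells of the mutant library (5.51). Several of these genes, fthl28, fthl31, ociad2, BX511021.1 and isg15, led cluster 44, so they partly define the mutant cells by the clustering. In cells with globin at 10 to 50% of UMIs in both libraries, ociad2 was at 8.85, fthl28 at 7.52, isg15 at 5.18, pon1 at 5.37, BX511021.1 at 5.08, hbegfa at 4.93 and hspd1 at 2.87.

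The single genes lower in mutant erythroid-like cells that the rule took included the transcription factor klf17, an alpha globin known by its synonym, and skeletal muscle genes. si:ch211-103n10.5 had 1182 UMIs in 210 wild-type cells and 0 in the mutant, 127-fold lower against the floor of 3 counts, with the interval ending at a log2 fold of -6.68. rfesd, a Rieske iron-sulfur domain gene, had 1381 and 11 UMIs (log2 -5.33, -6.34 to -4.49), and klf17 had 514 and 9 (-4.20, -5.34 to -3.26). cox4i1l, a cytochrome c oxidase subunit 4-like gene, had 325 UMIs and 1 UMI (-6.71, -12.02 to -4.22). anxa13l, an annexin, had 120 and 0 UMIs (at least 12.9-fold lower), and hspb1, a small heat shock protein, 101 and 0 (at least 10.8-fold lower). sult1st1, a sulfotransferase, was at -3.64, and histh1l, a linker histone, at -2.48 from 11209 and 648 UMIs. si:ch211-5k11.8 had 119 and 0 UMIs (at least 12.8-fold lower), and its wild-type UMIs were in 9 cells; the reference table gives it the synonym hbaa1.2, an alpha globin that the globin lists did not hold. myl1 (163 UMIs and 1 UMI), actc1b (-3.36) and tnni2a.4 (-3.51) are skeletal muscle genes. myl1 was at -5.71 (-11.02 to -3.21). All 3 were also lower in all other cells of the mutant library (-2.17, -2.57 and -3.07), where skeletal muscle-like cells were scarce. In cells with globin at 10 to 50% of UMIs in both libraries, the folds of histh1l (-1.19), actc1b (-1.10), tnni2a.4 (-1.36) and rfesd (-3.90) were smaller, with intervals that included 0 for actc1b and tnni2a.4, and klf17 was at -4.92.

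Outside the blood, retinal bipolar-like, photoreceptor-like, Müller or radial glia-like, lens-like and liver-like cells took larger shares of the mutant library, and neural progenitor-like and skeletal muscle-like cells smaller shares. Retinal bipolar-like cells numbered 173 and 1174, a share of 1.29% in the wild type and 7.97% in the mutant (6.18-fold higher, 5.26 to 7.29). Photoreceptor-like cells numbered 157 (1.17%) and 556 (3.77%), split over cluster 16 (156 and 426 cells) and cluster 39 (1 and 130). Müller or radial glia-like cells were at 0.768% and 2.86%, lens-like cells at 0.201% and 0.882%, and liver-like cells at 0.0298% (4 cells) and 0.258% (38 cells). Neural crest or glia-like cells were at 0.194% and 0.502%, and iridophore-like cells at 0.671% and 1.15%. Neural progenitor-like cells numbered 2584 (19.3%) and 419 (2.84%), 6.77-fold lower in the mutant (6.11 to 7.53). They fell in cluster 6 (1198 and 78 cells), cluster 7 (875 and 329) and cluster 19 (511 and 12). Clusters 6 and 19 were mostly from the wild-type library and may partly be that library rather than a cell type. Unnamed clusters with neural progenitor as their best match differed less: cluster 1 (1508 and 964 cells), cluster 9 (687 and 256) and cluster 10 (461 and 432). The 6.77-fold difference therefore holds for the named class only. Skeletal muscle-like cells numbered 144 (1.07%) and 8 (0.0543%). Fibroblast or mesenchyme-like cells were at 2.58% and 0.970% (2.66-fold lower), a difference that reversed with at most 10% mitochondrial UMIs (log2 1.03) and with doublets removed at the expected rate (1.97). All of them were in cluster 21. Unnamed clusters with fibroblast or mesenchyme as their best match went the other way: cluster 32 (61 and 119 cells) and cluster 37 (42 and 108). Sizes of these differences moved with the settings. With no doublet removal the log2 fold of the neural progenitor-like share was -4.67 (from -2.76), that of the bipolar-like share 3.84 (from 2.63) and that of the lens-like share 0.58 (from 2.13). The photoreceptor-like share was at 2.79 with clustering resolution 2 (from 1.69), and the liver-like share at 1.31 with at least 500 genes and 3.73 with at most 10% mitochondrial UMIs (from 3.11). The skeletal muscle-like share of cells was at -3.17 with doublets removed at the expected rate (from -4.31), and with at least 500 genes no mutant cell was left in the class. Shares of unnamed clusters were 58.6% and 73.1%.

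The shares of other blood and supporting classes differed by less than 1.5-fold. Macrophage-like cells were at 1.41% and 1.77% and neutrophil-like cells at 0.142% (19 cells) and 0.210% (31 cells). Endothelium-like cells were at 0.648% and 0.679% and superficial epidermis-like cells at 0.239% and 0.265%. Melanophore-like (1.26% and 0.889%), xanthophore-like (0.976% and 0.651%) and muscle progenitor-like cells (0.991% and 0.665%) had lower shares in the mutant. The macrophage difference reversed with at least 500 genes (log2 -0.13) and at clustering resolution 2 (-0.24), and neutrophil-like cells were at -0.45 with at least 500 genes.

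Across 22 other classes and clusters of at least 100 cells per library, genes of the mitochondrial genome, mitochondrial chaperones and the antioxidant response were mostly higher in the mutant library. The median of all measured genes was itself above 0 in each of them (log2 0.0493 to 0.35). Mitochondrial genome medians lay above it in all 22 (0.24 to 1.09), mitochondrial chaperones in 20 (0.12 to 1.05 over the 22) and iron-sulfur cluster assembly in 21 (0.11 to 0.91), the last above percentile 50 of matched random lists in 15. The antioxidant response lay above it in 21 (-0.70 in macrophage-like cells to 1.45 over the 22), the nuclear respiratory chain in 17 and glycolysis in 11. Hypoxia targets lay above it in 0 of 21 and below 0 in 17 (median of medians -0.20), but at 0.43 over all other cells together. Signs of RNA quality moved too, with a median mitochondrial share of UMIs per kept cell of 2.72% and 5.52% and ribosomal protein genes at 26.4% and 17.9% of the non-globin UMIs of all other cells. The integrated stress response lay above it in 17 of 22 (median of medians 0.37, highest 0.97), compared with 1.56 in erythroid-like cells. G2/M medians were above 0 in 11 classes and below in 11, from -1.51 in photoreceptor-like cells to 1.75 in cluster 12, and the S phase median was below 0 in 7 and above in 15; they lay above the median of all genes in 7 and 12. Taken over all other cells together, the medians of S phase (-0.75) and G2/M (-1.04) were lower in the mutant, as were the thinned shares of G2/M-positive cells, 21.0% and 9.43% (unthinned 62.7% and 52.4%).

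Genes with UMIs shifted across classes included gngt2b on the mutant side and 4 embryonic globins on the wild-type side. Free RNA of red cells and cones can place such UMIs in cells of other classes, so they are not read as expression there; globins took 0.135% and 0.00395% of UMIs outside the erythroid-like class. gngt2b, a cone phototransduction gene, was higher in 11 of 11 classes (median log2 3.94), as were CR361551.1 (6 classes, 3.74), itpr1b, an IP3 receptor (6 classes, 3.50), and trpm1b, a channel of bipolar cells and pigment cells (5 classes, 3.42). A further uncharacterised gene was higher in 12 classes (3.69). Over all other cells together gngt2b was at 3.73 CPM in the wild type and 622 CPM in the mutant. si:ch211-57n23.4 (-6.22 over 6 classes) and the globins hbbe1.3 (-6.09 over 22), hbbe3 (-5.95), hbae1.3 (-5.83) and hbbe1.2 (-5.83) were lower. Other genes were shifted in a class but little by median over the other classes where they were measured, which were few. These were 2 classes for hand2, fthl29 and fabp11b, 1 for zgc:153184 and PDE9A, and 4 to 10 for the rest, so specificity to a class was not shown. hand2, a transcription factor of autonomic neurons, was higher in cluster 12, whose leading genes were phox2a and phox2bb (1 UMI and 377 UMIs, log2 7.89, 5.40 to 13.19). In photoreceptor-like cells, of which cluster 39 was nearly all mutant, tcima had 1 UMI and 486 UMIs (7.01, 4.52 to 12.31), and zgc:153184 had 0 and 243 (at least 21.4-fold higher). PDE9A was higher in cluster 14 (3 and 310 UMIs, 5.40, 3.84 to 7.69) and fthl29, whose value is uncertain as one of the ferritin-like family, in cluster 18 (7 and 559 UMIs, 4.88), beside 5.99 in erythroid-like cells and 1.14 over all other cells together. Lower were fabp11b, a fatty acid-binding protein, in photoreceptor-like cells (103 and 17 UMIs, -4.52), zgc:77784 in cluster 11 (-3.22), si:ch211-286o17.1 (-3.55) and the homeobox gene meis1a (-3.66) in neural progenitor-like cells, whose largest cluster was cluster 6 in the wild type and cluster 7 in the mutant, and the WNT agonist rspo2 in cluster 18 (-3.33).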

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

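Alternatives with at least 10% globin UMIs, with doublets removed at the expected rate, with all barcodes, with globin at 10 to 50%, with fewer than 10 neuron marker UMIs and for shares of other classes were chosen after seeing the data, the others before. Among results that answer a comparison, 68 values stayed within the counting interval, 37 moved beyond it in the same direction and 11 reversed. Among all others 642 stayed, 298 moved and 33 reversed. The erythroid-like share of cells and the G2/M cells among erythroid-like cells stayed within their intervals in every alternative run, at -4.47 to -3.87 and -1.37 to -0.19. No paired analysis was possible because each genotype had 1 library. The number of cells limits the mutant side, with 72 erythroid-like cells, not depth per cell (medians of 1780 and 9573 non-globin UMIs). All values are log2 of mutant over wild type, and except where a sentence says otherwise the cause was not tested.

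With at least 100 genes the globin share was -1.0008, the heme synthesis list -0.20, the G2/M list -1.64, the S phase list -1.04 (reversed), S phase cells -1.02 (reversed) and hmbsb 0.0462 (reversed). With at least 500 genes the globin share was -0.97, the G2/M list -1.78, the S phase list -1.15 (reversed) and S phase cells -1.31 (reversed). With at most 10% mitochondrial UMIs the globin share was -1.0009, heme synthesis -0.19, G2/M -1.62, S phase -1.03 (reversed), S phase cells -1.0026 (reversed), hmbsb 0.0647 (reversed) and the fibroblast-like share 1.03 (reversed). The erythroid-like clusters held 24, 1 and 47 mutant cells in the main setting, and 9 and 47 with at least 100 genes. They held 5 and 50 with at least 500 genes, and 8 and 48 with at most 10% mitochondrial UMIs. Values of the erythroid-like class in these settings lay near those in cells with at least 10% globin UMIs. Whether the same mutant cells were left out was not examined. With no doublet removal the globin share was -1.27, heme synthesis -0.0883, S phase 0.22 and alad 0.0279 (reversed). With globins and cell cycle lists kept among the variable genes the globin share was -1.10, G2/M -1.68 and S phase -0.0557 (reversed). With doublets removed at the expected rate in both libraries the globin share was -1.28, S phase 0.38, G2/M -1.05, alad 0.12 (reversed) and the fibroblast-like share 1.97 (reversed). The erythroid-like clusters then held 14 and 34 mutant cells, fewer than the 72 of the main class. Their wild-type cells numbered 1140 and 1, against 1134 in the main class. The macrophage-like share was -0.13 with at least 500 genes and -0.24 at resolution 2, both reversed. The fibroblast-like share had a value in 4 alternatives, because no cluster took the name in the rest.

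With CPM of all UMIs, which adds 1.24 to each fold by construction, slc25a37 was -0.0319, iron-sulfur cluster assembly 1.91, S phase 1.94 and G2/M -0.0415. Reversed there were heme synthesis 0.88, alad 1.02, hmbsa 0.27, hmbsb 0.94, uros 0.43, urod 0.71, cpox 0.0641, fech 0.59, abcb10 0.82, the mitochondrial genome 0.72 and the erythroid regulators 0.041. With median-of-ratios scaling slc25a37 was -1.76, heme synthesis -0.84, iron-sulfur cluster assembly 0.18, S phase 0.21 and G2/M -1.77. With ambient RNA subtracted S phase was 0.82. With equal weight per cell heme synthesis was 0.0697, alad 0.14, hmbsb 0.24 and urod 0.0001, all reversed. With list members of at least 100 UMIs, which takes fewer genes, iron-sulfur cluster assembly was 0.27.

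In cells with at least 10% globin UMIs the globin share was -1.0003, heme synthesis -0.17, G2/M -1.61, S phase -1.03 (reversed), S phase cells -1.01 (reversed) and hmbsb 0.0741 (reversed); this setting leaves out 5 wild-type and 16 mutant cells. In all barcodes with at least 10% globin UMIs the globin share was -0.89, slc25a37 -0.78, iron-sulfur cluster assembly 0.84 and G2/M -1.49, and reversed were heme synthesis 0.19, S phase -1.50, S phase cells -1.21, alad 0.21, hmbsb 0.38 and urod 0.16. In cells with globin at 10 to 50% of UMIs slc25a37 was -0.83, and reversed were heme synthesis 0.0475, S phase -1.88, alad 0.13, uros 0.0808 and abcb10 0.0582. In cells with fewer than 10 neuron marker UMIs, which leaves out 11 wild-type and 10 mutant cells, the globin share was -1.31 and S phase 0.86.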

Other observations

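The tests named in this part were chosen after the result was seen, except the erythroid-like share without doublet removal, which was planned. The 16 mutant erythroid-like cells under 10% globin held most of the mutant UMIs of 2 genes that were picked after their values were seen. myb, a transcription factor of blood progenitors, had 31 UMIs in the wild-type and 101 in the mutant class, and 30 and 11 in the cells with at least 10% globin. pfn1 had 292 and 736 UMIs in the class and 292 and 48 in the cells with at least 10% globin. Over all 9 blood progenitor markers most mutant UMIs (534 of 733) lay in the cells with at least 10% globin. After thinning, 8 of these 16 mutant cells and 2 of the 5 wild-type cells under 10% globin were S phase-positive; before thinning the shares were 100% and 60.0%.

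Macrophage-like cells, all from cluster 23 (189 and 261 cells), differed from erythroid-like cells in some lists and went the same way in others. In the mutant library glycolysis genes were lower there (median log2 -1.10, percentile 0 over 18 members), as were antioxidant genes (-0.70, 21 members), interferon and inflammation genes (-1.56, 7 members), heme breakdown genes (-0.60, 6 members), nuclear respiratory chain genes (-0.28, 44 members) and dissociation stress genes, a sign of handling (-0.33, percentile 0.8, 18 members). Erythroid regulators and membrane genes (2.098, 14 members) and the mitochondrial genome (0.57, 13 members) were higher there. In the same direction as over all erythroid-like cells were G2/M (-0.58, percentile 0), S phase (0.48, 0.25 to 0.70, percentile 99.87) and the integrated stress response (0.31, 0.13 to 0.64, percentile 86.3), although S phase was lower in erythroid-like cells with at least 10% globin. In cluster 12, whose leading genes were phox2a and phox2bb, both cell cycle lists were higher in the mutant, S phase at 1.88 and G2/M at 1.75.

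The first pattern is the lower share of erythroid-like cells in the mutant library. Lysis in the suspension would leave free globin RNA, yet globin outside the class was 0.0293 times the wild-type share (0.00395% and 0.135% of UMIs). A lower share of all blood cells is argued against by macrophage-like and neutrophil-like cells at 1.28 times the wild-type share (1.07 to 1.53; the macrophage-like share alone stayed between log2 -0.24 and 0.31 in its alternatives), and doublet removal by a ratio of 0.0684 without it. A loss tied to the genotype may account for the difference, as a hypothesis, but a difference in stage or sampling between the single libraries stays open. Lysis and loss of cell debris before loading was not tested.

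The second pattern is the set of genes higher in mutant erythroid-like cells. For macrophages that took up red cells, 13 macrophage markers were examined in mutant erythroid-like cells, with a median of 0% of macrophage-like levels. The most abundant, mfap4 and apoeb (1169 and 1098 CPM in mutant macrophage-like cells), had 0 UMIs and 1 UMI in the erythroid-like cells. The class therefore held little macrophage RNA. Clustering could place such macrophages with macrophage-like cells, so their absence was partly built in and does not decide the question. In macrophage-like cells, erythroid regulators and membrane genes were higher in the mutant library (median log2 2.098, 14 members). The source of that RNA was not tested. For cells captured together with neurons, the median log2 fold over all 458 genes that passed the size rule upward was examined. It was 1.47 in all cells and 1.51 (1.49 to 1.58) without cells holding at least 10 neuron marker UMIs. The size rule required a mutant level at least 0.5 times that in all other cells, a limit meant to leave out RNA of other cells. That median could therefore hardly fall, and it does not decide the question for genes outside the 458. A lower maturity of the mutant cells could account for part of the pattern, since that median was 0.84 in cells with globin at 10 to 50% (74 wild-type and 50 mutant cells, 374 genes still higher), and a few early cells could add to it, since it was 1.18 (1.16 to 1.26) without cells under 10% globin, with 422 still higher. These 2 explanations, first tested on the 12 named genes (median 6.91 in all cells, 5.63 and 7.33), cannot be told apart from one tied to the genotype, because the median kept 0.574 of its size in the first test, between the bounds of 0.5 and 0.8, and 0.807 in the second, within counting error of the upper bound. The first test took globin share as maturity, but that share also falls as non-globin UMIs rise. Mean globin UMIs per cell were 5135 in the wild type and 5458 in the mutant in cells with at least 10% globin. The 74 wild-type cells had low globin shares for the wild-type class, whose 10th percentile was 55.4%. The lower median in the first test therefore does not by itself show lower maturity.

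The third pattern is the larger share of photoreceptor-like and bipolar-like cells in the mutant library. More eye tissue alone would keep the share of opsin-rich barcodes among crx barcodes alike, but that share was 46.9 times higher in the mutant (2 of 957 and 239 of 2438 barcodes with at least 10 opsin UMIs). This bears on opsin-rich cells only, not on bipolar-like cells (173 and 1174). Barcodes with crx were themselves more frequent in the mutant (957 of 17939 and 2438 of 16347), and so were lens-like cells (0.201% and 0.882%). More eye tissue therefore stays open for the rest of the pattern. For opsin-rich cells, doublet removal is argued against by all deposited barcodes, where the ratio was 154 (2 and 280 barcodes). A more advanced stage of the mutant embryos may account for this and for the lower share of neural progenitor-like cells, as a hypothesis that was not tested. Genotype and stage are confounded here, with 1 library each.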
